A study of Caenorhabditis elegans with 2 samples.

How the data were processed

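ChIP-seq of a D1046.2 fusion to green fluorescent protein was done on whole L4 larvae, with 2 biological replicates in 1 group per the labels. The files hold peak lists on the ce11 build. For each replicate and for both together there was a list of all candidate regions ranked by the irreproducible discovery rate (IDR) and a list of those past a threshold. A conservative and an optimal list combine both replicates, which makes 4 thresholded and 4 ranked lists. The peak caller, the aligner and the threshold are not given in the sources used here, and the control library was not analysed.

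The signal of each peak is the authors' own deposited value, on a scale that is not given in the sources used here, and it was used only to describe and rank peaks within a list. The score is the deposited IDR score, scaled and of a lowest value of 830 in all 4 thresholded lists. The ranked lists hold the global IDR as a deposited -log10 value, and its lowest value among the conservative peaks was 2.00, an IDR of 0.01. The ranked list that compares the replicates was told apart from the other by its values: 81.9% of its first set of per-replicate values recurred in the ranked list of replicate 1 and 79.0% of its second set in that of replicate 2, with 0% crossed. Per-replicate signals in the text come from each replicate's own ranked list, from the region that overlaps the peak with the nearest summit.

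Peaks were compared with the Ensembl annotation and the RefSeq sequence of the reference genome. No peak reached past the end of any of the 6 chromosomes, and 87.6% of 19531 protein-coding genes had the same start and end in both annotations. A promoter reached from 500 bp upstream to 100 bp downstream of any annotated 5' end of a protein-coding gene. Where classes overlap, a summit was counted first as coding exon, then 5' UTR, 3' UTR, intron and intergenic.

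The conservative list was the main set, and the 105302 candidate regions of its ranked list that did not pass were the background. Promoter and class shares were tested with 100000 draws that kept the number per chromosome, and shares on the X chromosome and near small noncoding RNA genes with Fisher's exact test. Gene lists were tested with Fisher's exact test among the 11276 genes with a candidate region in the promoter. The lists were set by gene symbol: the Argonaute list also took in 13 algn genes among its 36, and 8 listed symbols matched no protein-coding gene. The 6-mers within 50 bp of the summit were compared with a window of the same size centred 250 bp away, on alternating sides, with an exact McNemar test. P-values were adjusted by the Benjamini-Hochberg method within each family, with a threshold of 0.05. Shares have 95% Wilson intervals. P-values and intervals cover only these samples and the counting of peaks, and neighbouring peaks are not independent.

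Genes were named by a rule fixed before the data were examined: those nearest to the 25 strongest conservative peaks, up to 4 members per list with the highest signal of a promoter peak, D1046.2 and unc-119. The 10 6-mers with the smallest p among those higher at summits and 9 preset ones were also named. The functions used to test shares, lists and 6-mers were tested on simulated data. A changed share was called in 40 of 40 simulations and an unchanged one in 1 of 40. A changed list was called in 40 of 40, with 2 of 1320 unchanged lists called, and a planted 6-mer had the smallest p, with 0 of 2080 6-mers called in data without one. The simulated summits and flanks had the same base composition, unlike the real ones, so this does not test 6-mer calls that follow GC content.

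Alternatives were the optimal list, each replicate's own list in place of both, the stronger 50% of the peaks, merged peaks, other backgrounds, windows and distances, and k = 8. A planned stricter IDR of 0.01 is the threshold the lists already have, so the stronger 50% by signal was used for the shares, lists and 6-mers. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.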

Results

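Binding of D1046.2 was mapped by ChIP-seq in whole Caenorhabditis elegans at the L4 larval stage, 50 hours of age. The worms carried a transgene, made from a large genomic clone, that encodes D1046.2 fused to green fluorescent protein, and the fusion was pulled down with an antibody to that protein. There was 1 group with 2 biological replicates, so no comparison between conditions was possible, and the comparisons made here set peaks against other regions of the same experiment. Of the lists that combine both replicates, the conservative list held 1546 peaks and the optimal list 1641. Replicate 1 alone gave 619 peaks and replicate 2 alone 463. Read depth is unknown, because the files hold peaks and not reads, and the control library was not analysed here.

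The strongest peak lay upstream of eel-1, which encodes a HECT-domain ubiquitin ligase, on chromosome IV from 3050305 to 3050698 (ce11), in intergenic sequence with its summit 376 bp upstream of the nearest annotated 5' end. Its signal was 3151 in the pooled call, 1762 in replicate 1 and 1412 in replicate 2. Genes for proteins of the cytosolic ribosome followed: rpl-29 on chromosome IV from 13881800 to 13882105, with a signal of 1583, rpl-38 on chromosome V from 15511677 to 15511972, with 1253, and rpl-11.2 on chromosome X from 2242860 to 2243120, with 1224. The peak upstream of npp-3, a nucleoporin gene, had a signal of 1316 (chromosome II, 11874732 to 11875026), and that upstream of the synaptotagmin gene snt-2 had 1028 (chromosome III, 793642 to 793946). Of the 25 strongest peaks, 9 had a ribosomal protein gene as the nearest gene: besides those above, rpl-24.1, rps-17, rpl-6, rps-23, rpl-21 and rpl-3. Others lay at ify-1 (signal 978), T26A8.4 (822), ndub-8 (813), sec-61.A (805), trap-2 (714), ndk-1 (698), glit-1 (672), R04F11.2 (637), rsp-6 (637) and ccdc-12 (586). A second peak near eel-1 had a signal of 763, and a pair of peaks with K08F11.1 as the nearest gene had 720 and 712. The summits of 21 of these 25 peaks fell in a promoter.

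Both replicates found the strongest peaks. Of the 100 strongest peaks of replicate 1, 99 overlapped a peak of replicate 2, and 96 of the 100 strongest of replicate 2 overlapped a peak of replicate 1. Over the full lists, 47.3% of the replicate 1 peaks (95% Wilson interval 43.4 to 51.3) overlapped a replicate 2 peak by at least 1 bp, and 63.7% of the replicate 2 peaks (59.2 to 68.0) overlapped a replicate 1 peak. The conservative list covered 87.7% of the replicate 1 peaks and 89.8% of the replicate 2 peaks. Of the conservative peaks, 81.6% overlapped an optimal peak, and 76.7% of the optimal peaks overlapped a conservative one. Across the 1546 conservative peaks, the signals of both replicates had a Spearman correlation of 0.430 and a Pearson correlation of 0.795 on the log10 scale. Among the 100 strongest peaks the Spearman correlation was 0.835, and among the other 1446 it was 0.305. The conservative peaks were themselves selected for agreement between these replicates, so correlations within that list do not measure agreement over all regions. Over all candidates the Spearman correlation was 0.316. All these correlations are across peaks, which are not independent replicates, so no p-value is given.

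Promoters of protein-coding genes held 397 of the 1546 conservative summits, or 25.7%. Draws of as many other candidate regions from the same chromosomes gave a mean of 14.02%, with 95% of draws between 12.4% and 15.7% (two-sided permutation test, p = 2e-05, the smallest that the draws can give). The share was 80% among the 50 strongest peaks (66.96 to 88.8) and 17.3% (14.7 to 20.2) among peaks ranked from 801 to 1546. The median distance to the nearest protein-coding 5' end was 949 bp, against 1310 bp for 2000 other candidate regions drawn at random.

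**Figure D1:**
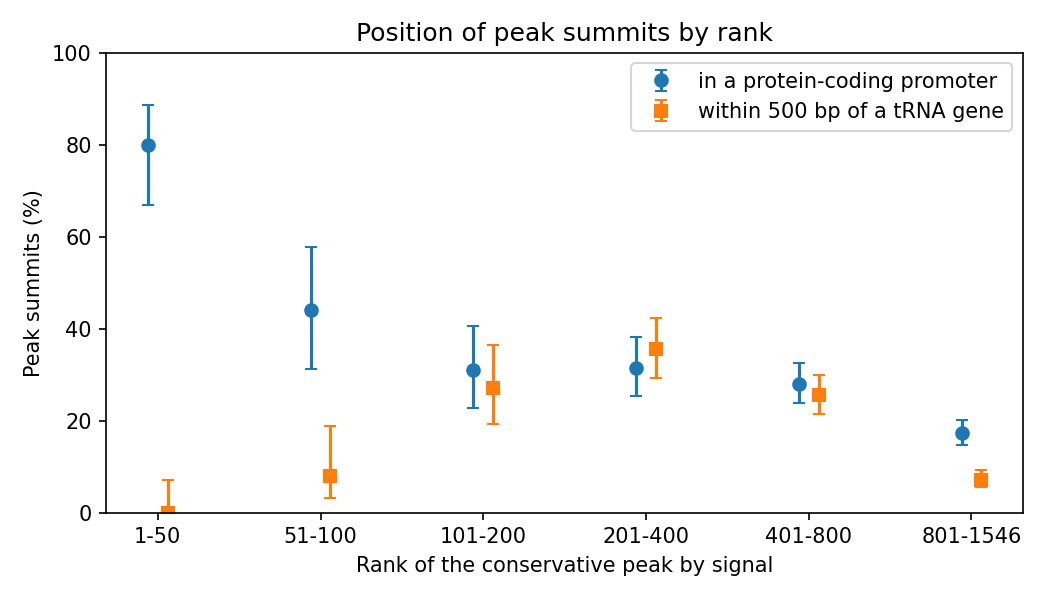
Share of conservative peak summits, in percent, that fell in a protein-coding promoter (circles) or within 500 bp of a tRNA gene (squares), by rank of the peak by signal, with 95% Wilson intervals as bars. The promoter share was 80% in the 50 strongest peaks and 17.3% in the weakest bin, and the tRNA share was highest, 35.5%, at ranks 201 to 400.

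Sequence between genes held 48.8% of the conservative summits against 31.1% in draws from the other candidates, and coding exons held 19.3% against 33.2% (both adjusted permutation p = 5e-05, permutation test with Benjamini-Hochberg adjustment over 5 classes). Introns held 27.4% against 31.6% (adjusted permutation p = 0.00047), 5' UTRs 2.20% against 1.45% (adjusted permutation p = 0.0317) and 3' UTRs 2.39% against 2.67% (adjusted permutation p = 0.560). In the list of replicate 2 alone, introns held 33.05% of summits and the difference from the draws was no longer past the threshold and had the opposite sign (adjusted permutation p = 0.587). The 5' UTR share stayed above its draws but did not pass in the optimal list, 2.07% (1.49 to 2.88) against 1.47% (adjusted permutation p = 0.0743). The same held in replicate 1 alone, 2.42% (1.47 to 3.96) against 1.44% (adjusted permutation p = 0.0857), and in replicate 2 alone, 1.94% (1.03 to 3.65) against 1.55% (adjusted permutation p = 0.587). Either replicate's own list holds fewer peaks. Coding exons held 8.08% of the summits in replicate 1 alone, 5.18% in replicate 2 alone and 7.89% among the stronger 50% of the conservative peaks.

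The X chromosome held 294 of the 1546 summits, 19.02% (17.1 to 21.05), against 16.7% of the other candidates (odds ratio 1.17, two-sided Fisher's exact test, p = 0.0179). The odds ratio was 1.07 in the optimal list (17.9%, 16.1 to 19.8, exact p = 0.273) and in replicate 1 alone (17.6%, 14.8 to 20.8, exact p = 0.516). It was larger, 1.24, in replicate 2 alone (20.3%, 16.9 to 24.2), where the test on 463 peaks did not pass (exact p = 0.0722). Against chromosome length the share did not pass either (exact binomial test, p = 0.172). It passed among the stronger 50% of peaks (20.8%, odds ratio 1.31, exact p = 0.00315) and with overlapping peaks merged (19.2%, exact p = 0.0108). Many of the tRNA genes with a peak, described below, lie on the X chromosome. The X share was 6% among the 50 strongest peaks, where 0% of summits lay near a tRNA gene. It was highest, 23.5%, at ranks 201 to 400, where 35.5% did. Whether the X share stays above its background without peaks near tRNA genes was not tested. The X share therefore does not show a preference for this chromosome apart from its tRNA genes. Peaks per megabase ranged from 10.8 on chromosome V to 19.95 on chromosome III.

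Transfer RNA genes were the most frequent small noncoding neighbours. Of the conservative summits, 257 lay within 500 bp of a tRNA gene, 16.6% (14.9 to 18.6), against 0.477% of the other candidates (odds ratio 41.6, adjusted exact p = 1.01e-275). Counted by gene, 299 of 612 annotated tRNA genes had a summit within that distance, with a median signal of 115 and a highest of 267, at a pair of tRNA genes on chromosome X at 3035976 to 3036047 and 3036164 to 3036235. Genes for small nucleolar RNAs lay near 71 summits, 4.59% against 0.428% (odds ratio 11.2, adjusted exact p = 1.45e-45). The one with the strongest peak was D1007.20 on chromosome I, whose peak, with a signal of 818, is the one upstream of rpl-24.1. Genes of the snRNA class lay near 18 summits, 1.16% against 0.127% (odds ratio 9.25, adjusted exact p = 1.55e-11). The one with the strongest peak was R07E5.16, with a signal of 281. Also among them were sls-2.4, sls-2.2 and sls-2.1, which encode SL2 spliced leader RNAs, with signals of 216, 207 and 197. MicroRNA genes lay near 14 summits, 0.906% against 0.288% (0.540 to 1.51, odds ratio 3.17, adjusted exact p = 0.000259). The microRNA test did not pass within 200 bp of the gene, where 5 summits were left (0.323%, 0.138 to 0.755, odds ratio 2.31, adjusted exact p = 0.0724). Nor did it pass in replicate 2 alone, with 4 summits and a share close to the main one (0.864%, 0.336 to 2.20, odds ratio 2.87, adjusted exact p = 0.0544). In replicate 1 alone, replicate 2 alone and the stronger 50% of peaks, the tRNA share was 20.7%, 26.8% and 26.1% and the snoRNA share 8.08%, 10.2% and 7.24%. The snRNA share was 1.78% in replicate 1 alone. All tests were two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 4 classes.

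A conservative peak lay in the promoter of 468 genes, 4.15% of the 11276 protein-coding genes that had any candidate region there. Proteins of the cytosolic ribosome stood out: 34 of the 71 tested genes had a peak, 47.9% (36.7 to 59.3), 21 of them for the large and 13 for the small subunit. The strongest were rpl-29, rpl-38, rpl-11.2 and rpl-22, the last sharing its peak with ify-1 (signal 978). The 34 genes lay at 33 different peaks, since rpl-24.1 and rps-10 share one. None of the 43 tested genes for mitochondrial ribosomal proteins had a peak (upper limit 8.20%), and the 2 groups differed (two-sided Fisher's exact test, p = 1.93e-09). Over the 34 lists fixed before the data were examined, 6 had peaks more often than other genes and 1 less often at an adjusted exact p under 0.05 (Fisher's exact test, Benjamini-Hochberg adjustment over the 34 lists). For the cytosolic ribosome the odds ratio was 22.8 and the adjusted exact p 5.50e-27. Genes were not matched for expression, and the control library was not analysed here. Differences between lists therefore do not show binding that is specific to D1046.2.

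Heat shock proteins and their cochaperones had a peak at 9 of 37 genes (adjusted exact p = 0.000253), with dnj-14, which shares its peak with glit-1, at a signal of 672, dnj-28 at 291, hsp-1 at 237 and hsp-3 at 232. The 9 genes lay at 8 different peaks, since hsp-16.2 and hsp-16.41 share one. In replicate 1 alone the count was 5 of 33 (15.2%, against 24.3% in the main list, adjusted exact p = 0.0131) and in replicate 2 alone 6 of 32 (18.8%, adjusted exact p = 0.000344). Oxidative phosphorylation genes had a peak at 7 of 30 (adjusted exact p = 0.00204): nuo-1, of complex I, which shares its peak with the ribosomal protein gene rpl-36.A, at 581, cox-5B at 220 and cox-5A at 197, both of cytochrome c oxidase, and atp-1, of the ATP synthase, at 139 were the strongest. In replicate 1 alone the count was 4 of 30 (13.3%, against 23.3% in the main list), just under the threshold (adjusted exact p = 0.0498), and in replicate 2 alone 5 of 29 (17.2%, adjusted exact p = 0.00177). Translation factors had a peak at 5 of 30 genes (odds ratio 4.66, adjusted exact p = 0.0407), among them ife-3 at 249, iff-2 at 223, eef-2 at 139 and eef-1A.2 at 103.98. Splicing genes had a peak at 5 of 31 (odds ratio 4.48, adjusted exact p = 0.0407), among them rsp-6 at 637, snr-1 at 129, and rsp-5 and snr-3, which share a peak, at 400. In the heterochronic pathway, which times larval development, 4 of 11 genes had a peak (adjusted exact p = 0.00651): lin-66 at 124, alg-1 at 97.4, daf-12 at 91.6 and lin-14 at 86.9. The heterochronic count fell to 1 gene in replicate 1 alone (adjusted exact p = 0.669) and to 0 in replicate 2 alone (adjusted exact p = 1). In replicate 2 alone, with fewer peaks in all, translation factors had 3 of 26 (11.5%, odds ratio 7.15, adjusted exact p = 0.0765) and splicing genes 3 of 30 (10%, odds ratio 6.09, adjusted exact p = 0.0944). Both odds ratios were above the main ones but not past the threshold, with 95% intervals of the shares up to 28.98% and 25.6%. Among the stronger 50% of peaks, splicing genes had 4 (odds ratio 4.97, adjusted exact p = 0.0588) and heterochronic genes 2 (odds ratio 8.34, adjusted exact p = 0.124), neither past the threshold.

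Chemoreceptor genes had a peak less often, at 7 of 462 (odds ratio 0.346, adjusted exact p = 0.0122), srh-269 having the strongest at 157, a peak that also lies within 500 bp of a tRNA gene. In replicate 1 alone the count was 2 of 415 (0.482%, adjusted exact p = 0.00954) and among the stronger 50% of peaks 4 of 460 (0.870%, adjusted exact p = 0.0287). In replicate 2 alone it was 2 of 493 (0.406%, 0.111 to 1.47, against 1.88% of other genes), an odds ratio of 0.212 that did not pass the threshold (adjusted exact p = 0.0765).

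The mitochondrial ribosomal proteins (adjusted exact p = 0.529) and the lists that follow, 27 in all, did not pass. Among genes of general cell functions, a peak was found at 2 of 6 chaperonin genes (cct-8 at 244 and cct-7, adjusted exact p = 0.0981), 2 of 19 proteasome genes (pas-4 at 432 and rpn-5 at 397), 4 of 34 histone genes (his-37 at 181, htz-1 at 140), 3 of 20 DNA replication genes (pcn-1 at 105, mcm-4 at 82.0, pola-1 at 73.8), 1 of 28 aminoacyl-tRNA synthetase genes (ears-2), 1 of 14 vacuolar ATPase genes (vha-8) and 1 of 26 genes of the Argonaute list (alg-1). Of the families that are large in worms, the counts were 1 of the collagens (col-71, 0.990% of those tested), 2 of 73 hedgehog-related and molting genes (wrt-3, nas-10), 3 of 143 nuclear hormone receptors (nhr-41, daf-12, nhr-68), 1 of 56 homeobox genes (ceh-45), 1 of 71 neuropeptides (flp-23), 1 of 48 ligand-gated channels (lgc-31), 2 of 174 F-box genes (fbxb-85, fbxa-133), 2 of 135 C-type lectins (clec-126, clec-145), 1 of 82 detoxification genes (gst-27), 0 of 5 vitellogenins and 0 of 19 major sperm proteins. Insulin and stress transcription genes had a peak at 2 of 22 (atf-6, zip-2) and vulval genes at 1 of 18 (egl-17). Of the tissue markers, a peak was found at 0 of 21 for muscle, 1 of 18 for intestine (fat-6), 0 of 20 for hypodermis, 1 of 20 for neurons (tbb-1), 1 of 27 for germline (nos-3, at 363) and 0 of 16 for pharynx. The peaks of nas-10, nhr-41, flp-23, lgc-31, clec-126 and egl-17 also lie within 500 bp of a tRNA gene, and without peaks near tRNA genes, an alternative chosen after seeing the data, the neuropeptide, ligand-gated channel and vulval counts were 0. With a promoter of 1000 bp upstream, chaperonin and histone genes also passed (adjusted exact p = 0.0225 and 0.000206), and F-box and C-type lectin genes passed as having fewer peaks (adjusted exact p = 0.0282 and 0.0400).

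**Figure D2:**
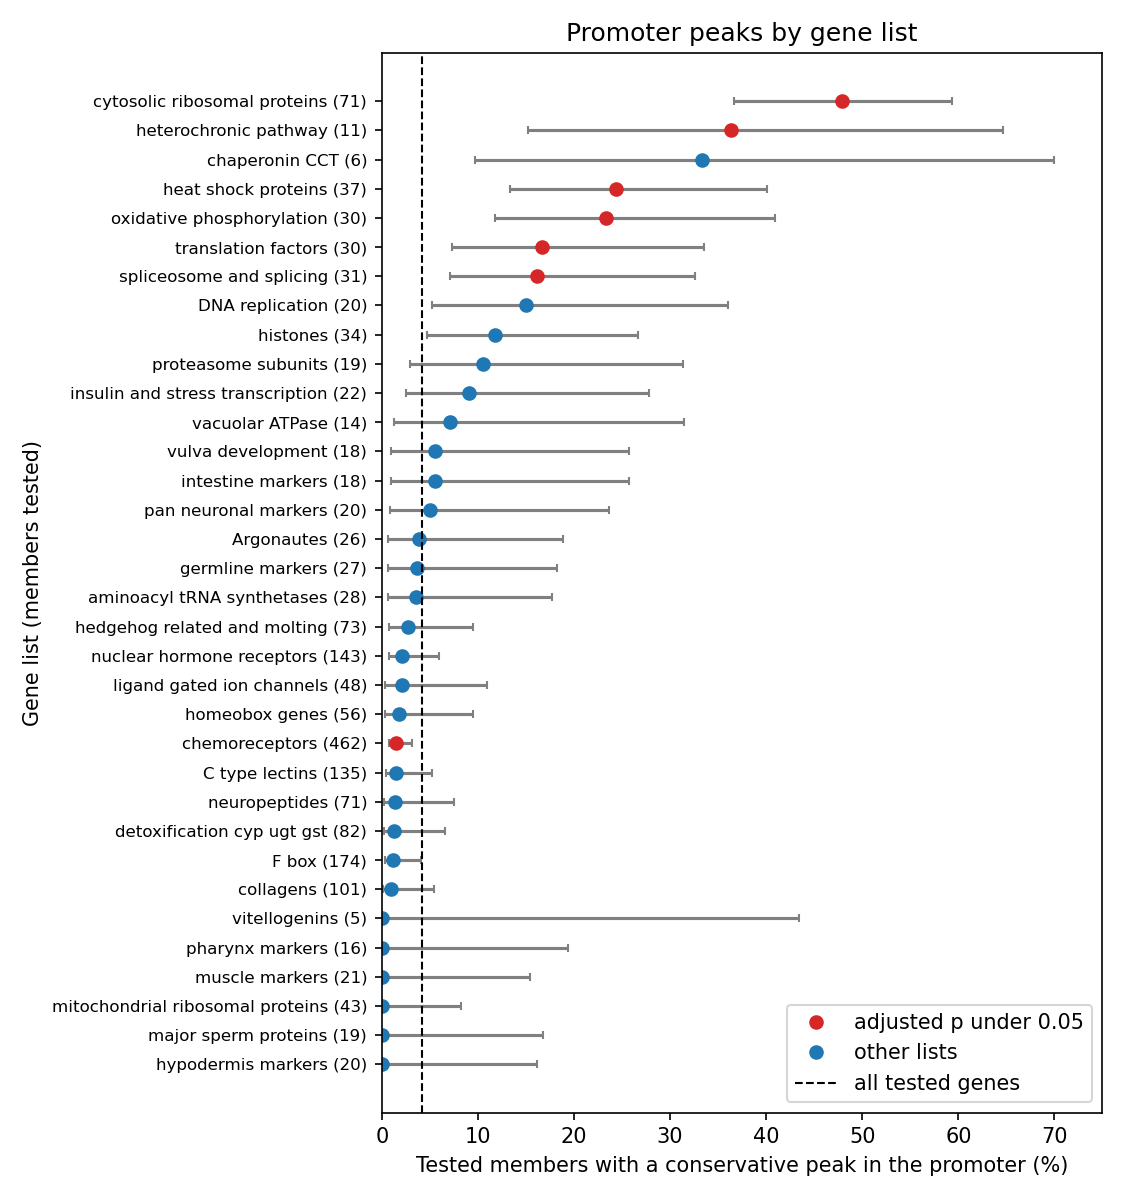
Percent of the tested genes of each of the 34 lists with a conservative peak in the promoter, with 95% Wilson intervals and the number of genes tested beside each name. The dashed line marks 4.15%, the share of all tested genes, and the cytosolic ribosomal proteins lie at 47.9%.

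Summits were richer in G and C than their flanks, 49.6% against 36.7% on average over 1546 pairs of windows. Of 2080 6-mers, each joined with its reverse complement, 662 were found at more summits than flanks and 390 at fewer (exact two-sided McNemar test, adjusted exact p under 0.05). No comparison of 6-mers was matched for GC content, so calls that follow base composition cannot be told apart from others. CGAACC had the smallest p among those more frequent at summits, in 11.97% of summit windows and 2.65% of flanks (adjusted exact p = 2.54e-22). It was followed by GCGCCA, CGCGCC, GAACCC, AGAGCG, GCGCGC, GAGCGC, ACGCGC, AGCGCG and CCGGCG. Both CGAACC and GAACCC lie in the reverse complement of GGGTTCGA, found in 5.30% of summit windows and 0.323% of flanks. GGGTTCGA was at 0% of the 50 strongest summits and 11% at ranks 201 to 400, where tRNA shares were 0% and 35.5%. Without peaks near tRNA genes, an alternative chosen after seeing the data, all 53 named lists and 6-mers kept their side of the threshold. GGGTTCGA is not among these 53. Keeping a side of the threshold does not show how much of the CGAACC and GAACCC excess comes from peaks near tRNA genes. The counts of 6-mers alone do not show a sequence recognised by D1046.2. Of the 9 6-mers fixed before the data were examined, GAGAGA (10.3% against 6.27%, adjusted exact p = 0.000206), CACGTG (4.27% against 1.75%, adjusted exact p = 0.000188) and GGGCGG, counted as CCGCCC (6.27% against 1.62%, adjusted exact p = 2.10e-10), were more frequent at summits. TGATAA, CTTATC, TATAAA, TTTTTT and TTTCAG were less frequent there, TATAAA with 3.23% against 10.4% (adjusted exact p = 3.60e-14), and TGACGT, counted as ACGTCA, did not differ past the threshold (2.72% against 2.85%, adjusted exact p = 0.960). In replicate 1 alone TGACGT was less frequent at summits, 1.13% against 4.20% (adjusted exact p = 0.00633). In replicate 2 alone it was found in 2.16% against 1.94% (adjusted exact p = 1). TATAAA was found there in 6.05% against 11.0% (adjusted exact p = 0.0388), and CGAACC, among the stronger 50% of peaks, in 18.1% against 2.20% (adjusted exact p = 1.81e-23). CACGTG, also in replicate 2 alone, had about the same shares as in the main list, 4.32% (2.81 to 6.58) against 1.73%, but did not pass (adjusted exact p = 0.0917). CTTATC, with 2.72% (2.02 to 3.65) against 4.33% in the main list, stayed lower at summits but did not pass in several alternatives, among them the optimal list (2.99%, 2.27 to 3.93, against 3.78%, adjusted exact p = 0.326).

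Candidate signal was high around the D1046.2 gene and not around unc-119, a rescue marker that, by the genotype label, the transgene carries. Within 20 kb of D1046.2 (chromosome IV, 8924167 to 8926067), 4 conservative peaks were found, the strongest from 8922111 to 8922406 with a signal of 136. The median signal of the 13 candidate regions there was 88.2, against 28.0 over all candidates, and lay above that of 99.2% of 1000 random windows of the same size. Within 20 kb of unc-119 (chromosome III, 10902641 to 10908935) there were 0 conservative peaks, and the 56 candidate regions had a median signal of 23.5. Copy number was not measured here at either locus. How much of either window the transgene carries is not known here, nor whether its unc-119 marker came from this locus. The low median around unc-119 therefore does not show that extra copies have no effect.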

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

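Both tests in this part were chosen after the result was seen. In each ranked list, some regions past the IDR of 0.01 are lacking from the matching thresholded list: 73 for the conservative list, 71 for the optimal list, 49 for replicate 1 and 43 for replicate 2. They drew attention as signal in data outside the comparisons. The strongest candidate region of all is among them, on chromosome X from 15810941 to 15811176, in intergenic sequence, with a signal of 3586.

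A removal of regions in multi-copy sequence is a candidate explanation. The 50 bases around the summit occurred more than once in the reference for 44 of the 73 lacking regions (60.3%) and for 158 of the 1546 kept peaks (10.2%) (two-sided Fisher's exact test, p = 1.80e-23). The tables argue against a stricter IDR threshold, since kept peaks reached down to a -log10 IDR of 2.00, the cut that the lacking regions had also passed. The median -log10 IDR was 3.13 for the lacking regions and 2.55 for the kept peaks. The deposited notes name, for the thresholded lists and not for the ranked ones, a further input file of unnamed content, which could be a list of excluded regions and was not tested. The 73 lacking regions lay at 40 loci on a 10 kb scale, so they are not independent in the test of copies. The 29 lacking regions with a single copy are not explained by their own sequence. Some of them lay beside multi-copy ones, such as that on chromosome V from 5284608 to 5284903. Whether whole loci were removed was not tested, and no biological explanation was tested.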

How the results depend on the processing

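The tests with a looser IDR, without peaks of pooled signal below 20, with lacking regions put back and without peaks near tRNA genes were chosen after seeing the data, and the other alternatives before. The shares in promoters, in coding exons, between genes and near tRNA, snRNA and snoRNA genes kept their direction and their side of the threshold in all alternatives run, though some sizes moved by over 1.5 times. Coding exons held 5.18% to 8.08% of summits and snoRNA genes lay near 8.08% to 10.2% in either replicate's own list, and tRNA genes near 26.8% without replicate 1. The results below changed, and the cause was not tested.

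In the optimal list, the X share was 17.9% and the 5' UTR share 2.07%, both still above their background but not past the threshold, and 5 peaks lay within 20 kb of D1046.2. Against chromosome length, the X share of 19.02% did not pass. Introns held 29.2% of the stronger 50% of peaks, not past the threshold, and there the splicing list (4 genes) and the heterochronic list (2 genes) lost their calls. Against random positions the 3' UTR share of 2.39% passed as lower. Within 200 bp, microRNA genes lay near 0.323% of summits, not past the threshold. With 1000 bp promoters, 3 lists had fewer peaks. With k = 8, 396 8-mers were more frequent at summits. Under 50% reciprocal overlap, the conservative list covered 83.8% of replicate 1 and 82.7% of replicate 2 peaks, and replicate 1 covered 58.96% of replicate 2 peaks. Over all candidates the Spearman correlation was 0.316. An IDR of 0.05 gave 4794 conservative, 5066 optimal, 1508 replicate 1 and 1114 replicate 2 peaks.

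With each replicate's own list in place of both, which holds fewer peaks, the X share was 17.6% to 20.3%, the 5' UTR share 1.94% to 2.42%, the intron share 26.8% to 33.05%, and the microRNA share 0.864% to 1.13%. Lists with more peaks numbered 3 to 5, lists with fewer 0 to 1, and genes with a promoter peak 195 to 289. There were 319 to 375 6-mers more frequent and 222 to 278 less frequent at summits, and 3 peaks near D1046.2 in either list. The intron share turned to higher than its background without replicate 1, and the heterochronic list had 0 genes with a peak there. Of the named lists and 6-mers, 491 of the results under an alternative kept their side of the threshold, 14 lost it, 5 gained it and 1 changed direction from a called one. Among the 491, the sign changed in 30, none of them past the threshold in the main list or the alternative. No paired analysis was possible because there is 1 group.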

Other observations

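The long sequence described here was noticed in strong peaks on several chromosomes, those later held out among them, before it was tested, and the genes at its sites, the SL2 count, the tests of sequence recognition and of repeats, the share of unique tRNA genes and the comparison at matched GC content were chosen after the data were seen. Among the 100 strongest peaks, ACCGTA was within 50 bp of 44 summits and 1 flank (exact McNemar test, adjusted p = 5.35e-09 over all 6-mers), and AACGAGTG of 23 summits and 0 flanks (adjusted p = 0.00265 over all 8-mers). ACGGTA was found in 48.0% of the 50 strongest summit windows and in 2.82% of those ranked from 801 to 1546. An 18-base consensus from 10 sites in strong peaks of chromosomes I, II and III read TACGGTAACACTCGTTTC.

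On chromosomes IV, V and X, which did not enter the consensus, 10 of 11 sites of this sequence with at most 1 mismatch lay within 50 bp of a conservative summit (90.9%, 95% Wilson interval 62.3 to 98.4). Over the genome 25 of 30 such sites did, a count that includes sites chosen for lying in strong peaks. Of 11 exact copies over the genome, 9 lay within 50 bp of a summit. Among these 9, intergenic copies lay upstream of npp-3 on chromosome II (11874848 to 11874865), rpl-11.2 on chromosome X (2242960 to 2242977), rpl-24.1 on chromosome I (4584861 to 4584878), rps-23 on chromosome IV (12391295 to 12391312), rpl-21 on chromosome III (8130518 to 8130535) and rpn-5, a proteasome gene, on chromosome II (4698444 to 4698461), and the copy nearest to rpl-19 lay in an intron. The strongest peak, upstream of eel-1, holds TACGGTCACACTCGTTTC on chromosome IV from 3050460 to 3050477. Of the 30 sites, 27 lay within 500 bp upstream of the nearest 5' end and 9 had a ribosomal protein gene as the nearest gene. The 5 sites without a conservative peak lay nearest to Y20F4.8, hrde-4, F54A3.6, rde-4 and Y73B3A.20. The sites at F54A3.6 and Y73B3A.20, the latter in a 5' UTR, are exact copies and had no candidate region within 50 bp.

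D1046.2, or a factor bound with it, may recognise this sequence at some peaks. Over the genome, 38 sites with at most 4 mismatches lay within 50 bp of a summit of the 1546 conservative peaks. Most conservative peaks therefore had no such match near the summit. On the same held-out chromosomes, 15 of 408 sites with at most 4 mismatches (3.68%) lay within 50 bp of a summit, against at most 1.31% for 100 shuffled sequences. The tables argue against copies of one repeat, since the 50 bases on either side of 38 sites near summits had a median pairwise identity of 28.0%. Whether ribosomal protein promoters are bound whatever their sequence stays open: on the same chromosomes the mean of the fewest mismatches was 4.83 ± 3.07 (SD) in 12 promoters with a peak and 6.73 ± 0.786 in 11 without (two-sided permutation test, p = 0.076), with a match of at most 4 mismatches in 5 of the 12 and 0 of the 11. The medians were 7 in both, which by the criterion set before the values were seen speaks for binding whatever the sequence, but after the unequal means were seen the test was read as undecided.

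Peaks at tRNA genes made up 16.6% of the conservative list, and the control library was not analysed here. Reads shared between identical gene copies could add to them, since 246 of 469 tRNA genes with an identical copy had a peak (52.5%) against 53 of 143 of unique sequence (37.1%) (odds ratio 1.87, two-sided Fisher's exact test, p = 0.00156). Neighbouring tRNA genes can share a peak, so genes are not independent in this test and its p may be too small. Genes of unique sequence had a peak in 37.1% of cases (29.6 to 45.2), while 1.58% of random windows of the same size held a summit. This cannot exclude shared reads there, since near-identical genes count as unique and neighbouring tRNA genes can share a peak. The tables argue against the sequence of the strong promoter summits, found with at most 6 mismatches at 7 of 257 summits and 14 of their flanks (exact McNemar test, p = 0.189). They also argue against GC content of the summit window as the whole cause. When weighted to the same GC content, 2.26% of candidates elsewhere passed, against 33.9% (30.6 to 37.3) of those near tRNA genes. A part of GC content stays open, as mean GC differed by 0.0767 percentage points between tRNA genes with and without a peak but the class is GC-rich throughout, and no biological explanation was tested.

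Of the 18 genes for SL2 spliced leader RNAs, 9 had a conservative summit within 500 bp, against 8 of the 111 other genes of the snRNA class, a difference that was not tested. The pooled signal was below 20 at 39 conservative peaks, and at all 39 a candidate region with more than 2 times the signal had its summit within 300 bp.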
